A study of Homo sapiens with 2 samples.

How the data were processed

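Total RNA was extracted from U87MG cells given control siRNA or siRNA against CDC42 and RAC1, 1 sample of each. Per the labels' protocols, Cy3-labelled cRNA was prepared by linear amplification and hybridised to Agilent one-colour arrays. The groups were taken from the labels, which do not say whether the cells came from separate cultures, which siRNA sequences were used or how long after transfection the RNA was taken.

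The deposited files hold spot intensity values on a linear scale, 1 file per array. Per the file headers, images were processed with Agilent Feature Extraction 12.0.3.1, whereas the submitters' processing notes name version 9.1. Per the file headers, the processed signal is the background-subtracted, detrended spot intensity with no normalization between arrays. The same deposited files hold the median pixel intensity of each spot and of its local background, the scanner's error for each processed signal, and flags for background, saturation and outliers. Per the file headers, the array design was built on hg19.

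Main values were log2 of the processed signal minus the array's 75th percentile over non-control spots. That percentile was a signal of 267 on the control array and 252 on the knockdown array. Spots flagged as outliers (113 and 98 non-control spots) or control spots were left out. A probe counted as measured when it was well above background on both arrays. The spots of a probe were averaged, then the probes of a gene, both on the log2 scale. The error of a difference combined the scanner's error of both arrays. For a gene with every probe at background on 1 array, a lower bound was formed. It set the bright array's value against the higher of the dim probe's own value and the lowest value well above background on the dim array.

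Probes were named through their RefSeq accession, without version, in a table of RefSeq genes on GRCh38.p14, used for names only. Of the 58201 probes 31104 matched 1 gene, none matched several and 27097 stayed unnamed. The named probes covered 22439 genes, of which 14640 were measured, 3812 of them with more than 1 probe. No coordinates are given, since the array and the gene table use different builds.

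With 1 array per group no test could be run, no p-value is given, and the number of arrays limits the precision. Before the data were examined, a size of 2-fold, the genes to be named and 33 gene lists were fixed. The named genes are both targets, the 12 with the largest difference each way among measured genes at or above the median brightness, the 4 largest bounds each way, and up to 4 members with the largest difference from each list described. Genes with no symbol, and some other loci by rule, were not named. Results for 1 gene of this rule and 2 of the 33 lists are not reported here. The percentile of a list's median is its place among 10000 random lists, drawn with replacement from the same 10 bins of brightness, and is descriptive. It treats genes as independent, so lists of genes that vary together will lie outside the range more often.

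Alternatives fixed before the data were examined were quantile normalization, the 50th percentile, the 75th percentile over probes well above background on both arrays, no background filter, the genes at or above the median brightness, the brightest probe of a gene, and limits of 1.5-fold and 3-fold. Normexp (limma 3.58.1 in R 4.3.3, offset 50), with quantile or 75th-percentile normalization, had been planned on mean signals and was run on median signals, a change made after the files were seen. Also added then were removal of the brightness trend (lowess, fraction 0.3), subtraction of the median difference of the 200 nearest spots, scaling on the E1A spike-in probes, and 10 further gene lists. For 3 of these lists, a 95% interval of the median was drawn by resampling members 10000 times.

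The computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6. It was tested on simulated data for the knockdown against control comparison with 15206 measured genes. At 2-fold it called none of 67 genes simulated at 1.5-fold, all (100%) of 67 at 2.5-fold and all of 66 at 4-fold. It called 0 of 14966 unchanged genes, and a list of 40 genes shifted by 0.25 gave a median of 0.245. In 100 draws of spot noise alone, from the probes printed 10 times, 0 genes reached 2-fold. These simulations hold no variation between cultures, and few dim probes were printed 10 times. The simulated knockdown array took its spot noise from those probes whatever the brightness, and its background flags from the control array. The simulations therefore do not show how often dim genes are called falsely.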

Results

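Gene expression was measured in U87MG cells, a human glioblastoma line with astrocytic features, after transfection with siRNA. The series asked which mRNA levels are affected when CDC42 and RAC1 are depleted together, and its title places this in work on the roles of these GTPases in Bergmann glia. CDC42 and RAC1 are small GTPases that direct actin assembly, cell polarity and migration. There were 2 one-colour arrays, 1 from cells given control siRNA and 1 from cells given siRNA against both genes. Each array held 62976 spots, of which 60901 were not controls, and these covered 58201 probes. In the control array 50.8% of non-control spots were well above background, and in the knockdown array 50.7% were. No non-control spot was saturated. The measured genes, those with a usable probe on both arrays, numbered 14640.

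Each group had 1 array, so no difference below has a replicate check and none was tested. Differences are the knockdown array minus the control array, in log2 units. The error given with a gene is the standard error from the scanner's error model, which was 0.20 for a bright gene with 1 probe and covers the array measurement only. The 180 probes printed 10 times on each array had a median SD of the difference of 0.050 between spots. A difference of at least 2-fold is therefore larger than spot-to-spot noise in bright probes, but it cannot be set against the spread between cultures.

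Both targeted transcripts were lower in the array labelled as the double knockdown. RAC1 was lower by 11.8-fold, a difference of -3.56 ± 0.20, with 8.46% of the control level remaining. The 10 spots of its probe had an SD of the difference of 0.10. CDC42 was lower by 3.64-fold over its 3 probes, a mean difference of -1.87 ± 0.12, with 27.4% remaining. The 3 CDC42 probes gave -1.71, -2.27 and -1.61, which left 30.5%, 20.7% and 32.7% of the control level. The last of these was designed on the RefSeq transcript NM_044472, and the first and second were designed on NM_001039802.

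**Figure D1:**
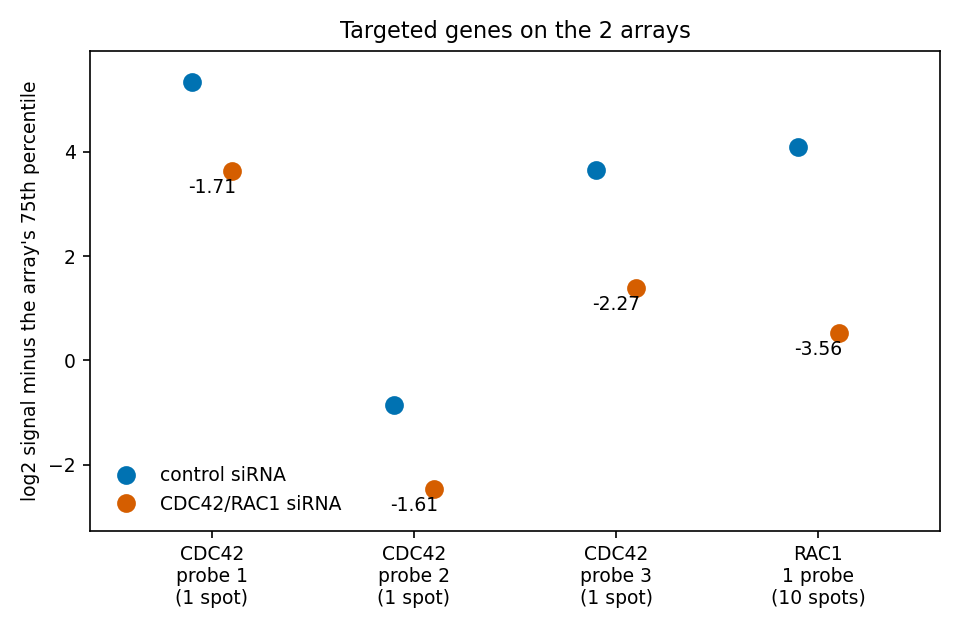
Level of each CDC42 and RAC1 probe on the control array (blue) and the knockdown array (orange), as log2 signal minus the array's 75th percentile; numbers give knockdown minus control. All 4 probes were lower on the knockdown array, by -1.61 to -3.56.

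Across the measured genes, 176 were at least 2-fold higher and 75 at least 2-fold lower in the knockdown array, together 1.71% of the total. The split leaned to higher genes, at 70.1%, and it depended on the scaling. It was 96 higher and 130 lower (42.5% higher) with arrays scaled to their 50th percentile, and 120 and 101 (54.3%) with spike-in scaling. It was 33 and 31 (51.6%) with normexp and quantile normalization of median signals, and 32 and 31 (50.8%) with normexp and the 75th percentile. Among the 7320 genes at or above the median brightness there were 19 higher and 14 lower (57.6%). Differences of at least 4-fold were found for 17 genes in each direction. Of the named genes at or above the median brightness, only RAC1 (11.8-fold lower) was among them.

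CHI3L1, a secreted glycoprotein of reactive astrocytes and glioblastoma, was 3.42-fold higher (1.77 ± 0.20). EIF4EBP2, which binds the cap-binding factor eIF4E and represses translation, was 2.66-fold higher (1.41 ± 0.14), with both probes at 1.33 or more. IFITM10 (1.31), the secreted and membrane protein SECTM1 (1.20) and the angiopoietin-like secreted protein ANGPTL2 (2.21-fold) were also at least 2-fold higher. So were PLAAT4 (1.14), the matrix glycoprotein EFEMP1 (1.14), FAIM2, an inhibitor of Fas-mediated death (1.11), ID3, an inhibitor of basic helix-loop-helix factors (1.10), and DEPP1 (1.07). Under 50th-percentile scaling SECTM1 (0.97), ANGPTL2 (0.92), PLAAT4 (0.91), EFEMP1 (0.91), FAIM2 (0.88), ID3 (0.88) and DEPP1 (0.85) were no longer 2-fold, nor were the last 5 under spike-in scaling. List members just past 2-fold on the higher side, given below, shift in the same way. The probe of RNA5-8SN5, the 5.8S ribosomal RNA, was 3.13-fold higher (1.65 ± 0.20). The other ribosomal RNA probes, chosen after their values were seen, gave -0.40 for RNA18SN5 and 0.07 for RNA28SN5.

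The named genes that were lower, apart from the targets, were led by inflammatory cytokines and chemokines. IL1B, the cytokine interleukin 1 beta, was at 40.0% of the control level (-1.32 ± 0.20) from a very bright probe. CSF3, the granulocyte colony-stimulating factor, was 2.48-fold lower (-1.31 ± 0.14), with its 2 probes at -1.42 and -1.20. PTGS2, the inducible cyclooxygenase, was 2.46-fold lower (-1.30 ± 0.20). The neutrophil-attracting chemokines CXCL3 (-1.21), CXCL1 (-1.18), CXCL8 (-1.15) and CXCL2 (-1.04) were all at least 2-fold lower. CXCL1, CXCL2 and CXCL3 are near-identical paralogs, and cross-hybridisation between their probes was not tested. The ErbB ligand NRG1 was 2.33-fold lower (-1.22 ± 0.14), with 2 probes at -1.26 and -1.17. The thrombin receptor THBD (-1.06) and the elastase inhibitor PI3 (-1.04) completed this set. CXCL2 was at -0.94 with the brightest probe, and PI3 at -0.99 under normexp with quantile normalization.

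**Figure D2:**
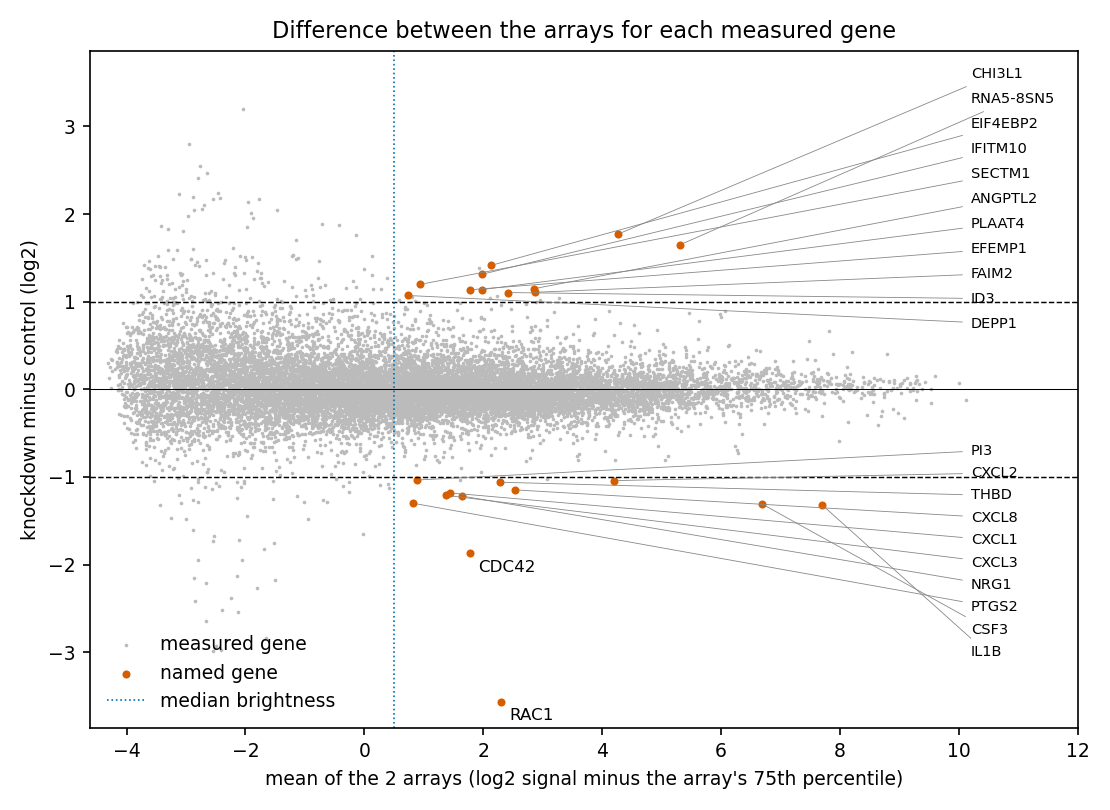
Knockdown minus control (log2, vertical axis) against the mean level of each of the 14640 measured genes (log2 signal minus the array's 75th percentile, horizontal axis), with dashed lines at 2-fold and the median brightness dotted. RAC1 and CDC42 lie furthest down to the right of that line, IL1B and CSF3 are very bright, and most 2-fold differences lie among dim genes.

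Most of the genes at 2-fold were dim, and probes of one gene differed more often there. Leaving out the targets, 22 probes at or above the median brightness of probes were at least 2-fold and had another measured probe of the same gene. For 17 of these probes (77.3%) the other probe was at least 1.5-fold in the same direction. A gene with several probes at 2-fold entered once for each, so agreeing probes count more than once and the shares are not shares of genes. Below the median brightness this held for 28 of 92 (30.4%). Among all probes of genes with several measured probes, 1.33% met it at or above the median brightness and 5.42% below it. The other probe was the brightest other one of the gene and could lie on either side of that median, so these shares are only a rough comparison. Probes of 5 genes, named after their values were seen, lay at least 0.5 from 0 in opposite directions. These were ADAMTS6 (lowest probe -1.64), NUTM2B (-0.59 to 0.51), OLFML2A (-0.90 to 0.98), UPF2 (-2.03 to 0.94) and ZNF302 (-0.53 to 1.81). Conflict between probes was not confined to them, since probes of further genes lay at least 1.5 apart in log2 units. Among those, also picked after their values were seen, EYA3 (-2.42 to 0.22), NPHP4 (0.13 to 2.39) and ZAN (-0.27 to 2.93) count at 2-fold through 1 deviating probe each.

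Genes seen on 1 array only have a bound in place of a difference. There were 529 genes well above background in the knockdown array alone, of which 213 had a bound of at least 2-fold higher. Another 552 were well above background in the control array alone, and 130 of these had a bound of at least 2-fold lower. The largest bounds were at least 27.7-fold higher for the divergent transcript ADCY6-DT, 19.9-fold for C16orf78, 15.5-fold for SOX10, a glial transcription factor, and 15.5-fold for VAC14-AS1. In the other direction they were at least 16.9-fold lower for RASGRF2, a Ras and Rac exchange factor, 16.6-fold for PCDHA6, 16.1-fold for PCDHGB2 and 15.7-fold for CYP4F22. Each of these 8 rests on 1 probe. The excess of higher bounds depended on the setting, with 146 higher and 160 lower under 50th-percentile scaling, 152 and 155 under quantile normalization, and 29 and 51 under normexp with quantile normalization.

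Before the data were examined, 33 gene lists were fixed, of which 31 are reported here. The median of each was placed among 10000 random lists of the same size and brightness. A list is said to stand apart when its median lay outside the central 95% of those lists. This describes these 2 arrays, is not a test, and takes no account of genes that vary together. There were 10 lists that stood apart on the higher side and 5 on the lower side, where 1.65 in all would lie there by the definition of the percentiles. Scaling to the 50th percentile moved the median of all genes by -0.22 and spike-in scaling by -0.14, which changes the sign of small list medians but not their percentiles.

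**Figure D3:**
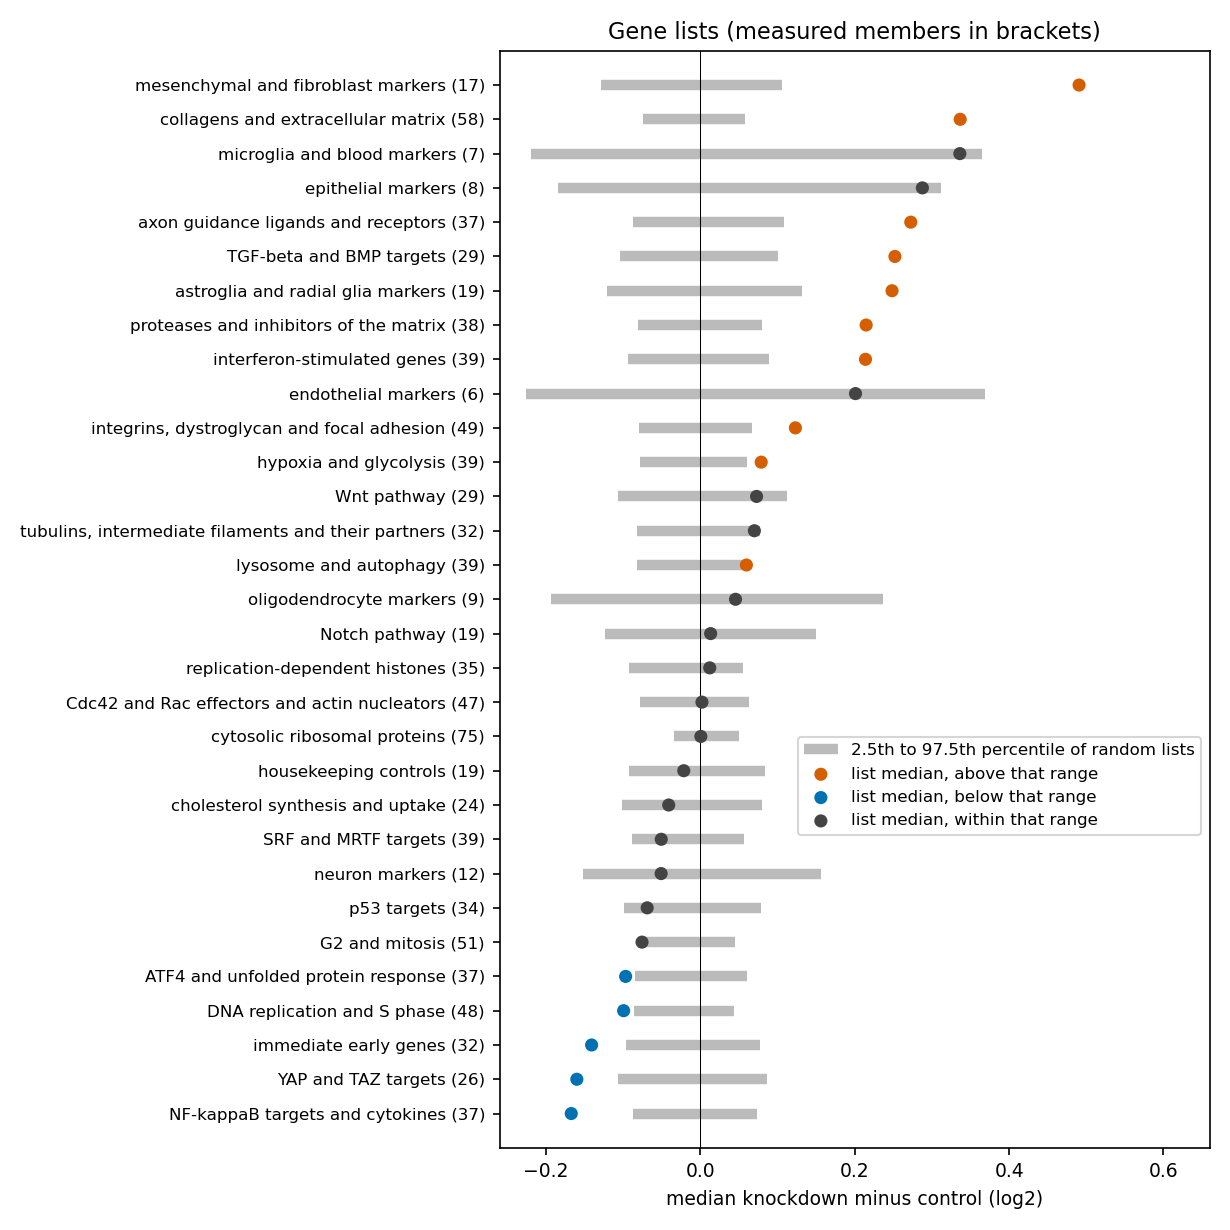
Median difference (knockdown minus control, log2) of 31 gene lists (points) with the central 95% of 10000 random lists of the same size and brightness (grey bars). Mesenchymal markers (0.49) and extracellular matrix genes (0.34) lie furthest above their bars, and NF-kappaB targets and cytokines (-0.17) and YAP and TAZ targets (-0.16) lie below; under 50th-percentile scaling all points move by -0.22, which puts 5 of the orange points (interferon-stimulated genes, proteases, integrins, hypoxia, lysosome) below 0, the last 3 of them also under spike-in scaling.

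NF-kappaB targets and cytokines were lower as a group, with 8 of 37 measured members at least 2-fold lower and none at least 2-fold higher. The list's median was -0.17, below all 10000 random lists, and 24 members lay below 0. Without the background filter the median was -0.11 (0.18th percentile). The 4 furthest from 0 were IL1B, CSF3, PTGS2 and CXCL3, and the other members at 2-fold were CXCL1, CXCL8, CXCL2 and the chemokine CCL20 (-1.11), the last named after its value was seen.

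Extracellular matrix genes were higher as a group. Of the 58 measured collagens and matrix genes 49 lay above 0, with 3 at least 2-fold higher and none at least 2-fold lower, and the median of 0.34 lay above all 10000 random lists. EFEMP1 (1.14), the fibrillar collagens COL5A1 (1.06, probes 0.85 and 1.26) and COL1A1 (1.02) passed 2-fold, and COL5A2 was at 0.91. Mesenchymal and fibroblast markers, 17 measured of which 5 are shared with the matrix list, had a median of 0.49, above all random lists. It was smaller under some settings, at 0.21 (99.8th percentile) among genes at or above the median brightness, 0.25 without the background filter and 0.24 and 0.26 under normexp. COL1A1, the receptor PDGFRB (0.87), fibronectin FN1 (0.85) and lumican LUM (0.67) were furthest from 0, and only COL1A1 passed 2-fold. Matrix proteases and their inhibitors had a median of 0.21 over 38 members, above all random lists, although it was -0.0088 under 50th-percentile scaling. In that list SERPINB2, an inhibitor of plasminogen activators, was at least 2-fold lower (-1.65), and TIMP3 (0.86), MMP15 (0.77) and ADAM19 (0.73) were higher by less than 2-fold. Integrins and focal adhesion genes had a median of 0.12 over 49 members (99.97th percentile), which was -0.10 under 50th-percentile and -0.016 under spike-in scaling. Of these, 2 passed 2-fold, ITGB8 (1.87) and the collagen receptor ITGA11 (1.14), and both lay below the median brightness. Among genes at or above the median brightness the integrin list no longer stood apart (0.045).

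TGF-beta and BMP targets had a median of 0.25 over 29 measured members, above all random lists, with 3 members at least 2-fold higher and 1 at least 2-fold lower. The 3 higher members were SMAD6 (1.19), ID3 (1.10) and ID2 (1.04, probes 1.03 and 1.05). The lower one was FST, a secreted binder of activin (-1.03). Interferon-stimulated genes had a median of 0.21 over 39 members, above all random lists, but -0.0096 under 50th-percentile scaling. In this list 32 members lay above 0 and 2 were at least 2-fold higher, the antiviral GTPase MX1 (2.01) and XAF1 (1.02). BST2 was at 0.96 and the GTPase GBP1 at -0.83, and all 4 came from dim probes.

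Axon guidance genes had a median of 0.27 over 37 members, above all random lists, with 1 member, the netrin NTNG2 (1.06), at least 2-fold higher. SEMA4D (0.85, probes 0.28 and 1.43), NTN4 (0.80) and SEMA3A (0.77) were next, and these 4 were dim. Astroglia and radial glia markers had a median of 0.25 over 19 members (99.96th percentile) and no member at 2-fold. The Hedgehog effector GLI1 was at 0.95, the radial glia fatty acid binder FABP7 at -0.92, the intermediate filament NES at 0.78 and NFIB at 0.73. Among genes at or above the median brightness this list's median was 0.091, no longer apart.

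Lists with smaller medians on the higher side were hypoxia and glycolysis, at 0.08 over 39 members (99.3rd percentile), and lysosome and autophagy, at 0.06 over 39 (98.3rd). Neither held a member at 2-fold, and the medians were -0.14 and -0.16 under 50th-percentile scaling and -0.061 and -0.080 under spike-in scaling. With normexp and quantile normalization of median signals neither stood apart (0.054 and 0.061). STC1 (-0.78) and HK2 (0.57, probes -0.13 and 1.28) were furthest from 0 in the first, and SQSTM1 (0.51) and CTSB (0.48) in the second.

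On the lower side, targets of YAP and TAZ, transcriptional co-activators that respond to cell shape, had a median of -0.16 over 26 members (0.13th percentile). None reached 2-fold. DLC1 (-0.59), GADD45A (-0.53), FJX1 (-0.45) and WWC1 (-0.42) were furthest from 0. Immediate early genes had a median of -0.14 over 32 members (0.080th percentile), yet 3 of the 4 members furthest from 0 were higher. These were KLF2 (1.04), SPRY4 (0.82, probes 0.21 and 1.42) and NR4A2 (0.60), and DUSP6 was at -0.64. DNA replication genes had a median of -0.10 over 48 members (0.82nd percentile), with none at 2-fold. RFC3 was at -0.40, GINS1 at 0.39, CDC6 at -0.29 and RRM2 at -0.28. ATF4 and unfolded protein response genes had a median of -0.10 over 37 members (1.23rd percentile). Their 1 member at 2-fold, the lipoprotein receptor VLDLR, was higher (1.06) with probes at 0.22 and 1.90. The YAP and TAZ, DNA replication and ATF4 lists no longer stood apart under normexp on median signals, nor did immediate early genes (-0.074) with quantile normalization after it. DNA replication also lost its place among genes at or above the median brightness (-0.069) and with the brightest probe (-0.069), and ATF4 after subtraction of the array surface (-0.061).

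**Figure D4:**
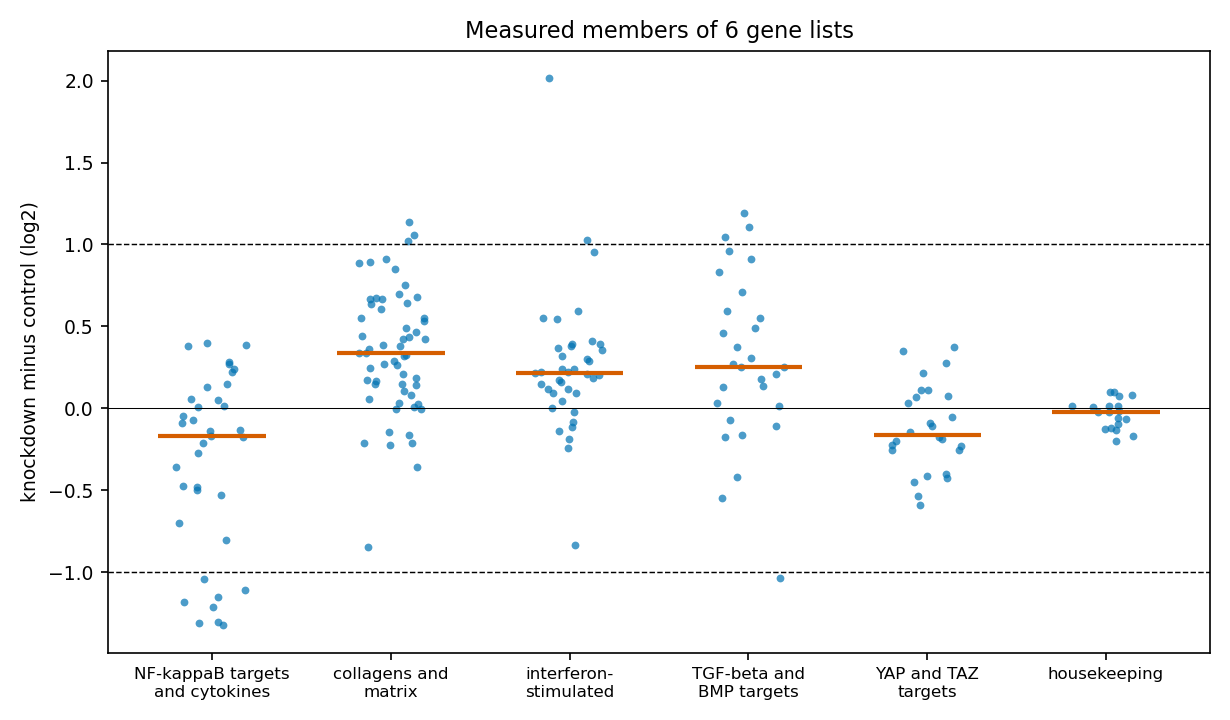
Knockdown minus control (log2) of each measured member (blue points) of 6 gene lists with the list median (orange bars) and dashed lines at 2-fold. The NF-kappaB and cytokine list has 8 members below the lower line and its lower quartile at -0.70, whereas matrix genes lie mostly above 0 (49 of 58) and housekeeping genes lie close to 0; under 50th-percentile scaling every median is lower by 0.22, and that of the interferon-stimulated genes is then -0.0096.

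The effectors of the targets did not stand apart. Cdc42 and Rac effectors and actin nucleators had a median of 0.0021 over 47 members (59.8th percentile), with the kinase PAK6 (0.98) and WAS (0.77), both dim, furthest from 0. SRF and MRTF targets had a median of -0.05 over 39 (16.3rd), with ACTG2 at -0.70 and JUNB at 0.57. Neither list held a member at 2-fold.

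The remaining lists also lay within the range of random lists. Medians and percentiles were -0.08 (3.66th) for G2 and mitosis, -0.07 (10.26th) for p53 targets, 0.01 (54.7th) for Notch, 0.07 (90.0th) for Wnt and -0.04 (24.96th) for cholesterol synthesis. They were 0.07 (96.3rd) for tubulins and intermediate filaments, 0.01 (79.1st) for histones, 0.00069 (37.7th) for ribosomal proteins and -0.02 (32.4th) for housekeeping genes. Markers of other cell types gave -0.05 (26.6th) for neurons, 0.05 (63.5th) for oligodendrocytes and 0.34 (96.4th) for microglia and blood. Endothelial markers gave 0.20 (85.0th) and epithelial markers 0.29 (96.6th). In these lists HBA2 (2.19), OLIG2 (1.48), PECAM1 (2.46-fold) and KRT19 (1.20) were at least 2-fold higher, each from 1 dim probe. Under 50th-percentile scaling the medians above 0 here, other than those of the microglia and blood (0.11) and epithelial (0.064) lists, lay below 0. The neuron median was 0.25 without the background filter and 0.29 (99.9th percentile), outside the range, among genes at or above the median brightness. The G2 and mitosis, p53, tubulin, microglia and blood, and epithelial lists stood apart under 1 or more alternatives.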

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

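Probes that match no named gene lie outside the gene comparison, and a number of them differed between the arrays. Of 7196 unnamed probes measured on both arrays, 131 were at least 2-fold higher and 96 at least 2-fold lower in the knockdown array. What they detect was not analysed here.

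The E1A spike-in probes, which detect a control RNA and not the cells, lay outside the comparison too. After scaling to the 75th percentile their median difference was 0.15, from 0.13 to 0.17 over 8 probes, where the median of all genes was -0.00048.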

How the results depend on the processing

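No paired analysis was possible because each group has 1 array. Normexp on median signals, lowess, the array surface and spike-in scaling were chosen after the data were seen. Of 404 comparisons of a main result with an alternative, 337 were labelled the same. That label includes medians of lists within the random range that changed sign, such as Wnt at -0.15 under the 50th percentile. The NF-kappaB, matrix, TGF-beta, axon guidance and mesenchymal lists stood apart, with their main direction, under all 11 alternatives run on lists. The 50th percentile, the 75th percentile over probes well above background on both arrays and spike-in scaling only shift all genes alike. List percentiles under them are therefore the main ones by construction, and results kept in this way count among the 337. The TGF-beta and axon guidance medians were only 0.028 and 0.049 under the 50th percentile, and the mesenchymal median was 0.21 among genes at or above the median brightness and 0.24 under normexp with quantile normalization. The 23 named genes kept their direction under the same 11 alternatives, but not all stayed at 2-fold. Among genes at or above the median brightness their values were the main ones by construction. Under the 50th percentile SECTM1 (0.97), ANGPTL2 (0.92), PLAAT4 (0.91), EFEMP1 (0.91), FAIM2 (0.88), ID3 (0.88) and DEPP1 (0.85) did not. Under spike-in scaling PLAAT4 (0.998), EFEMP1 (0.996), FAIM2 (0.967), ID3 (0.964) and DEPP1 (0.931) did not. Nor did CXCL2 (-0.94) with the brightest probe, FAIM2 (0.993) under normexp with the 75th percentile, or PI3 (-0.990 and -0.998) and DEPP1 (0.915 and 0.903) under normexp with quantile normalization and with the 75th percentile. Unless a cause is given below, the cause was not tested. Signal over background limits the dim genes, from which most counts at 2-fold came, and the number of arrays limits the precision of all values.

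The 50th percentile (a signal of 14.5 on the control array, where the lowest well above background was 11.5) moved all genes by -0.22, so differences shifted by construction. CDC42 was then -2.09 and RAC1 -3.79, with 96 genes higher and 130 lower. Among the lists that stood apart, the signs of 5 turned with their percentiles kept: hypoxia and glycolysis -0.14, integrins -0.10, interferon-stimulated genes -0.0096, lysosome -0.16 and proteases -0.0088. Spike-in scaling moved all genes by -0.14. CDC42 was then -2.01, and among the lists that stood apart hypoxia and glycolysis (-0.061), integrins (-0.016) and lysosome (-0.080) turned. Several lists within the range turned under both scalings too. Relative to all genes the integrin list stayed at 0.12 under both.

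Without the background filter 1219 genes were higher and 460 lower, among 22439 genes, and the tubulin list (0.090) stood apart. Since most genes at 2-fold were dim, only 19 were higher and 14 lower among the 7320 genes at or above the median brightness. There the neuron list turned to 0.29 (99.9th percentile), and DNA replication (-0.069), astroglia (0.091) and integrins (0.045) no longer stood apart. With the brightest probe CDC42 was -1.71, DNA replication (-0.069) no longer stood apart and tubulins (0.079) did. A limit of 1.5-fold gave 719 higher and 267 lower, and 416 bounds higher and 191 lower. A limit of 3-fold gave 33 and 27, and 93 bounds higher and 99 lower.

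Normexp with quantile normalization gave -1.60 for CDC42 and -3.32 for RAC1, 33 genes higher and 31 lower, and 29 bounds higher and 51 lower. Of those genes 62 were among the 251 of the main setting; its offset of 50 shrinks differences of dim genes by construction. YAP and TAZ (-0.068), DNA replication (-0.056), ATF4 (-0.046), hypoxia and glycolysis (0.054), immediate early genes (-0.074) and lysosome (0.061) no longer stood apart. Epithelial (0.16), microglia and blood (0.19) and tubulin lists (0.077) did. Normexp with the 75th percentile gave -1.61 and -3.34, 32 higher and 31 lower, and 35 and 50 bounds. YAP and TAZ (-0.078), DNA replication (-0.082), ATF4 (-0.070) and lysosome (0.035) no longer stood apart, while microglia and blood (0.26) and tubulins (0.063) did.

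Quantile normalization of processed signals brought G2 and mitosis (-0.069), p53 targets (-0.095) and microglia and blood (0.37) outside the range. Lowess did so for p53 targets (-0.093) and microglia and blood (0.37), and hypoxia and glycolysis (0.065) came within it. After subtraction of the array surface G2 and mitosis (-0.097) stood apart, and ATF4 (-0.061) and hypoxia and glycolysis (0.051) did not.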

Other observations

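The 10 gene lists described here, the brightness and array-surface corrections and the test of TGF-beta signalling were chosen after the main results were seen. Metallothioneins, small metal-binding proteins, had a median of -0.31 over 9 measured genes, below all 10000 random lists and below 0 under all scalings tried. MT1M (-0.72), MT1E (-0.59) and MT1F (-0.52) were furthest from 0, and cross-hybridisation among these close paralogs was not tested. Genes activated by NRF2, the regulator of the antioxidant response, had a median of 0.13 over 24 (99.9th percentile), but -0.092 under 50th-percentile and -0.0075 under spike-in scaling. In that list the aldo-keto reductases AKR1B10 (0.96, probes 0.94 and 0.97) and AKR1C3 (0.72) and the transporter ABCC3 (0.69) were furthest from 0.

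Secreted CXC and CC chemokines had a median of -0.82 over 11 genes and 5 at least 2-fold lower, all of them members of the NF-kappaB list. Of the others CCL3 was at -0.82 and 5 lay above 0, among them CXCL12 at 0.03, CCL2 at 0.28 and CCL26 at 0.86. Without the background filter the median was 0.18 over 20 genes (41.6th percentile), within the range of random lists, so the lower median holds for measured chemokines only. Small nuclear and nucleolar RNAs had a median of -0.04 over 204 (0.18th percentile) and MHC class I genes 0.09 over 16 (98.0th), the latter -0.13 under 50th-percentile scaling. The MHC list no longer stood apart without the background filter (97.2nd percentile), with the brightest probe (94.4th), after lowess (96.0th) or under normexp with either scaling (90.6th and 93.5th). The median of the small RNAs was 0.011 without the filter, still low among random lists (0.02nd percentile), as the median of all genes was then 0.096. Hedgehog targets (-0.09 over 9, 14.5th) and nuclear genes of the respiratory chain (0.03 over 41, 85.2nd) did not stand apart, except the first without the filter (1.86th).

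Lower NF-kappaB targets and cytokines were the first pattern weighed. After removal of the brightness trend the list's median was -0.17, and after subtraction of the array surface -0.18, each below all random lists. Both results argue against such a bias as the whole cause. Lower activity of NF-kappaB as a whole predicts lower feedback genes of the pathway. Yet these 14 genes had a median of 0.030 (72.4th percentile, 95% interval -0.066 to 0.22), above a limit of -0.10. That limit was set before this median was taken, but the main list had been seen, and 9 of the 14 are also on it. The median was -0.19 under 50th-percentile and -0.11 under spike-in scaling, both below the limit, with the percentile unchanged. The limit therefore does not decide, and the percentile shows only that these genes were not lower than others of like brightness. A more selective effect on secreted cytokines, an effect of the siRNA sequences on other genes and a difference between the cultures stay open and untested with 1 array per group.

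Higher collagens and extracellular matrix genes were the second. The list's median was 0.36 after removal of the brightness trend and 0.34 after subtraction of the array surface, both above all random lists, which argues against either as the whole cause. Higher TGF-beta signalling is a candidate explanation. Its 11 immediate targets had a median of 0.071 (80.4th percentile, 95% interval -0.11 to 0.25), and they went both ways, 6 above 0 and 5 below, with TGFBI at 0.55. The median was -0.15 under 50th-percentile and -0.068 under spike-in scaling, with the percentile unchanged. The data do not decide whether TGF-beta signalling was higher, and a difference in density or age between the cultures stays open and untested.

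Higher interferon-stimulated genes were the third. After removal of the brightness trend their median was 0.23, above all random lists, which argues against that bias as the whole cause. A response to double-stranded RNA, such as siRNA, could be a cause, although both arrays came from transfected cells. Genes of that response had a median of 0.18 (99.2nd percentile, 95% interval 0.044 to 0.24), below a limit of 0.21 by less than their spread. That limit equals the interferon list's own median, and was set before this median was taken but after the main results were seen. The median was -0.040 under 50th-percentile and 0.044 under spike-in scaling, with the percentile unchanged. Since 14 of the 15 belong to the interferon list itself, these values do not separate the explanations.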
